A study of Mus musculus with 15 samples.

How the data were processed

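RNA of sorted mouse skin tumour cells was copied to cDNA with a SMART-Seq v4 kit, per the labels' protocols. The kit does not mark strand. The deposited values are whole-number read counts per Ensembl gene, with no normalization. Per the submitters' processing notes, STAR 2.3.0, Picard 1.100, HTSeq 0.6.0 and the build mm9 were used, with no role given for each tool, and the annotation release is not given in the sources used here. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

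The deposited tables hold counts for 37583 genes. The 5 closing entries that name no gene were left out of library sizes and tests. Reads aligned to several places made up 29.86% to 38.04% of the records, reads outside genes 2.61% to 5.13% and reads in more than 1 gene 1.86% to 2.2%. Reads aligned to several places were not counted for genes, so levels of genes with near-identical copies are uncertain, and without strand the reads of overlapping antisense genes cannot be told apart. Symbols were matched by gene identifier for 32860 genes (87.4%), which held at least 99.5% of the counts in each library. The annotation at hand (GENCODE M21) belongs to another build and served for names, gene classes and gene order only, and no coordinates are given. Depth was 10.08 to 28.62 M gene counts per library, which is precise for abundant genes, but the number of libraries limits each comparison.

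Groups were genotype and population as the labels give them, with 2 KO and 3 WT libraries per population. Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr by group) in 1 fit of all 15 libraries with a coefficient per group, with Benjamini-Hochberg adjustment at 0.05 within each comparison. The fit tested 14652 genes. Standard errors of log2 fold changes were derived from the F statistic. KO against WT over all populations used counts summed per genotype and replicate number (15597 genes), since same-numbered libraries may share an animal. CPM values were computed on TMM-scaled library sizes. The 24 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list moves on balance in 1 direction and does not compare it with other genes. Adjusted p-values of lists are over the lists of 1 of the 8 comparisons.

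Comparisons, tests, lists and the naming rule were fixed before the data were examined. The rule names Sirt6, Itga6 and Cd34 in every library. It then takes genes past the threshold with a logCPM of at least 2 that differ in the same direction in both genotypes or, between genotypes, without overlap of the libraries. Of these it names the 8 with the largest rise and the 8 with the largest fall, leaving out predicted genes and pseudogenes, and it adds the 2 to 4 members of each list with the smallest p. Not all list members so chosen are printed. Krt10, Ddx3y, Tyrp1, Dct and the genes named in the a6 comparison without 2 libraries were chosen after their values were seen.

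Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 33.1 to 282), so none was taken as a repeat deposit. Whether same-numbered libraries of a genotype pair was checked by the correlation of their deviations from the group means. It was 0.136 to 0.473 over the 5 pairs of CD34-positive and CD34-negative a6-high libraries, above 0.1 in each, so these were taken as pairs, a pairing that comes from the data and not from the labels. With 2 KO libraries per group the deviations of KO replicates 1 and 2 mirror each other, so both KO pairs give the same value and the 5 pairs hold 4 separate values. It was 0.035 to 0.465 between a6-high and a6-low libraries, above 0.1 in 4 of 5, and -0.396 to 0.061 between KO and WT libraries of the same number, which were not taken as pairs.

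The tests were tried on simulated counts with 200 changed genes. For the CD34 comparison 12% of 2-fold and 70% of 4-fold changes were recovered, with 3 false calls among 85, and for a6 10% and 64%. For KO against WT 4% and 36% were recovered in CD34-positive a6-high, 3% and 38% in CD34-negative a6-high and 4% and 37% in CD34-negative a6-low cells, and 6% and 50% in the sums. False calls were 3 among 77 for a6. For KO against WT they were 0 among 40, 0 among 41 and 1 among 42 in the 3 populations, and 5 among 61 in the sums. The simulated libraries varied independently, with no effect shared by libraries of the same animal label. The figures for CD34 and a6 may thus differ from those for the real, correlated libraries. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a filter of at least 10 CPM in 2 libraries, a fit of the compared groups only, a replicate block (the animal label for CD34, a6 and the interactions, the replicate number for KO against WT) and leaving out each library. Added after the data were seen were fits without the 2 a6-low libraries at the a6-high level of Itga6, fits without the 3 libraries that express Y-linked genes, limma 3.58.1 (voom) with the animal label as a random block, and list tests without each library, in the 2 fits without several libraries, with DESeq2 size factors and with the animal label as a block.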

Results

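The series profiled RNA of mouse skin tumour cells from C57BL/6 animals. Tumours had been induced with DMBA, a mutagen, and TPA, a phorbol ester that promotes tumour growth. Cells were sorted by flow cytometry on CD34 and integrin alpha 6 (a6, encoded by Itga6) into 3 populations, CD34-positive a6-high, CD34-negative a6-high and CD34-negative a6-low. CD34 marks cells of the mouse hair follicle bulge, and a6 is a laminin receptor of basal keratinocytes. Animals were wild type (WT) or carried floxed alleles of the histone deacetylase gene Sirt6 with a Cre recombinase under the K14 promoter, which is active in keratinocytes (KO). Each population was represented by 2 KO and 3 WT libraries, 15 in all. Between 10.08 and 28.62 M reads (M, 1e6) per library were counted in genes (median 20.27 M). The 6 KO libraries held 23.02 ± 3.19 M (SD) and the 9 WT libraries 16.14 ± 3.87 M, and 15885 to 19380 genes were detected per library. Krt14, the keratin gene of basal keratinocytes, was the most abundant gene in every library with 2.85% to 6.95% of the counts.

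The targeted gene Sirt6 (ENSMUSG00000034748) was measured first. It lay at 5.07 to 8.53 CPM (gene counts per 1e6 counts of the library) in the 6 libraries labelled KO and at 4.45 to 10.5 CPM in the 9 WT libraries, so the ranges overlapped. The counts cover the whole gene and the labels do not say which exons were floxed, so Sirt6 does not check the genotype label, and the text speaks of libraries labelled KO. Cd34 (ENSMUSG00000016494) averaged 185 ± 20.3 CPM (SD, n = 5) in CD34-positive a6-high and 16.1 ± 4.67 CPM in CD34-negative a6-high libraries. Itga6 (ENSMUSG00000027111) lay at 263 to 576 CPM in the 10 a6-high libraries. In a6-low libraries it was 67.9 CPM in KO replicate 1, 94.1 CPM in WT replicate 2 and 174 CPM in WT replicate 3, but 471 CPM in WT replicate 1 and 446 CPM in KO replicate 2. Krt10, a keratin gene of suprabasal cells, was at 8555, 12270 and 5777 CPM in the first 3 of these a6-low libraries and at 2837 and 1833 CPM in the last 2. The Y-linked gene Ddx3y lay at 51.8 to 74.9 CPM in the 3 libraries of KO replicate 2 and at 0.222 CPM or less in the other 12.

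**Figure D1:**
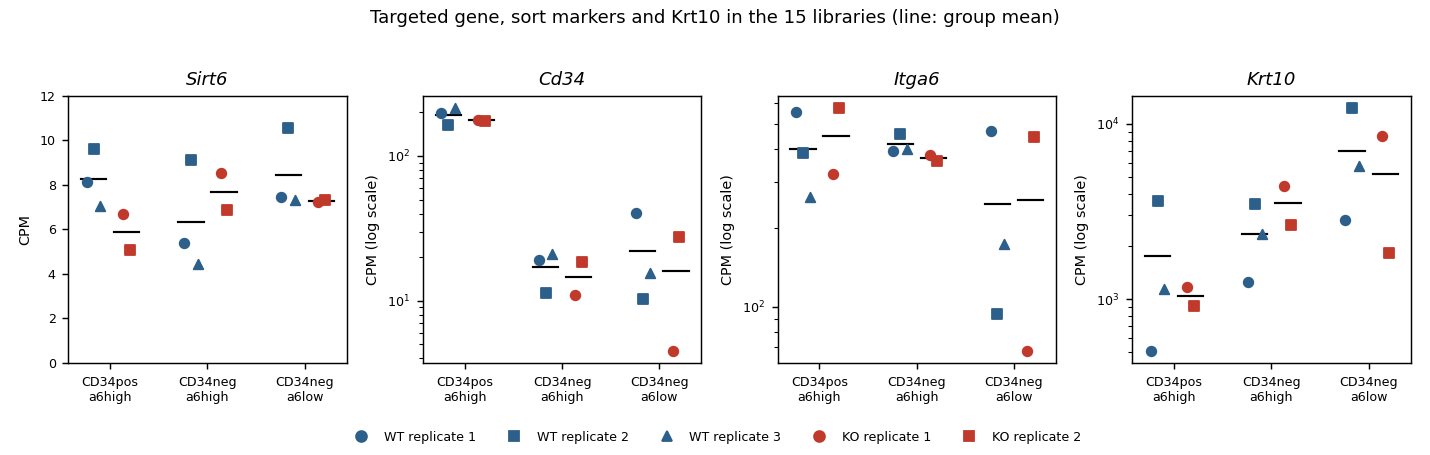
CPM of Sirt6 (linear axis), Cd34, Itga6 and Krt10 (log axes) in each of the 15 libraries by population, with WT in blue, KO in red, a symbol per replicate number and a black line at the group mean. The a6-low libraries of WT replicate 1 and KO replicate 2, with 471 and 446 CPM of Itga6, lie at the level of the a6-high libraries.

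Between CD34-positive and CD34-negative a6-high cells, the largest rises among the genes chosen by the naming rule were in Spp1, which encodes the secreted protein osteopontin (20.2-fold, log2 4.33 ± 0.73 SE, adjusted p = 0.0141), Aspa, which encodes aspartoacylase (12.3-fold, log2 3.62 ± 0.45, adjusted p = 0.00786), and the forkhead factor gene Foxe1 (11.9-fold, log2 3.57 ± 0.53, adjusted p = 0.00895). The tight junction genes Cldn17 and Cldn8 rose 11.7-fold and 10.4-fold, the fatty acid desaturase gene Fads2 10.1-fold and the glutathione S-transferase gene Gsta3 9.51-fold. Cd34 rose 11.6-fold, which reflects the sort and is no finding. The largest fall was in Postn, which encodes the matrix protein periostin, with 3.58 ± 3.64 CPM (SD, n = 5) in CD34-positive and 172 ± 107 CPM in CD34-negative libraries (log2 -5.54 ± 0.93 SE, adjusted p = 0.0135). In CD34-negative a6-high libraries Postn was at 7.90 CPM in WT replicate 3 and at 121 to 262 CPM in the other 4. The prostaglandin dehydrogenase gene Hpgd averaged 0.554 against 16.6 CPM, the ligand gene Wnt3 2.05 against 40.7 CPM, the prolactin receptor gene Prlr 0.681 against 6.03 CPM, the prolyl hydroxylase gene P4ha3 1.55 against 14.9 CPM, the neurotrophin gene Ntf3 0.846 against 10.1 CPM, the receptor gene Tnfrsf19 8.04 against 36.5 CPM and the carboxypeptidase gene Scpep1 44.1 against 253 CPM, and all 7 fell. In all, 124 genes rose and 47 fell, 171 of 14652 tested (edgeR quasi-likelihood test, mean of the WT and KO differences).

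With the animal label as a block, 793 genes passed in the CD34 comparison, 488 higher and 305 lower, and these included all 171. The count moved more than 1.5-fold without any 1 of 9 of the 10 a6-high libraries. It was 162 without the other, the CD34-negative library of WT replicate 3. Without a CD34-negative a6-high library it was 7 (KO replicate 1), 49 (KO replicate 2), 101 (WT replicate 1) or 99 (WT replicate 2). Without a CD34-positive library it was 44 (KO replicate 1), 102 (KO replicate 2), 110 (WT replicate 1), 258 (WT replicate 2) or 84 (WT replicate 3). Without the 3 libraries that express Y-linked genes it was 32, of which 21 were among the 171.

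Genes of glutathione metabolism and antioxidant defence were higher in CD34-positive a6-high cells, least so in WT replicate 2. There the list mean of log2(CPM + 1) was 7.65 against 7.25, and it was 8.13 to 8.31 against 7.41 to 7.51 in the other 4 pairs. Of 25 genes of the list 9 rose and 0 fell over all tested genes, and 11 rose and 0 fell adjusted over the list alone. The transferase gene Gsto1 averaged 11500 ± 2230 against 3932 ± 536 CPM (SD, n = 5) and rose 2.92-fold (adjusted p = 0.00445), Gsta4 rose 3.74-fold (adjusted p = 0.00786) and the glutathione peroxidase gene Gpx2 4.70-fold (adjusted p = 0.00834). The cystine transporter gene Slc7a11 averaged 78.2 ± 55.6 against 9.26 ± 4.80 CPM and rose 7.92-fold (adjusted p = 0.0256). Gclc and Gclm, which encode the subunits of the enzyme of the first step of glutathione synthesis, rose 2.53-fold and 2.13-fold, and the quinone reductase gene Nqo1, the catalase gene Cat and the transferase gene Gstp1 rose 2.15-fold, 1.93-fold and 1.72-fold. The list had a median log2 difference of 0.74 (camera adjusted p = 3.9e-13). Of the lists called in the CD34 comparison it alone kept its call with an estimated correlation (adjusted p = 0.0253), and fry gave an adjusted p of 0.000843. In the pentose phosphate pathway, which supplies NADPH, Pgd rose 1.86-fold (adjusted p = 0.0475), and 3 of 9 genes rose adjusted over the list alone (camera adjusted p = 0.00588, with an estimated correlation adjusted p = 0.0961). Fry gave this list an adjusted p of 0.000843.

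**Figure D2:**
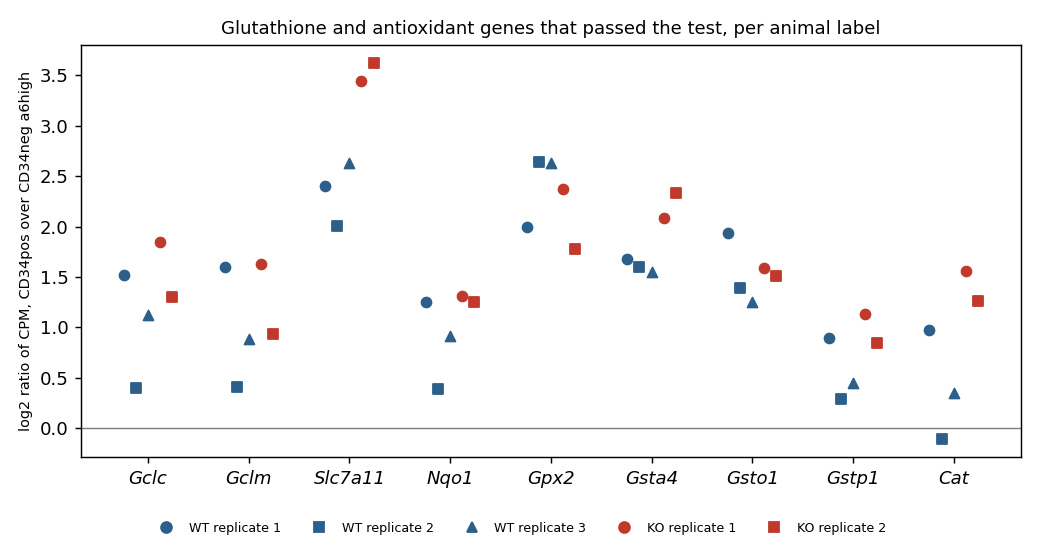
Log2 ratio of CPM in the CD34-positive over the CD34-negative a6-high library of the same genotype and replicate number (vertical axis) for the 9 glutathione and antioxidant genes that passed the test, with WT in blue, KO in red and a symbol per replicate number. Of the 45 ratios, 44 lie above 0, and that of Cat in WT replicate 2 lies below it.

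The series title speaks of glycolytic tumour-propagating cells. Of 23 glycolysis genes 0 rose and 0 fell over all tested genes, and 2 rose adjusted over the list alone. These were Ldha, which encodes a lactate dehydrogenase subunit (6466 ± 1760 against 3407 ± 360 CPM, SD, n = 5, 1.88-fold, adjusted p = 0.06 over all genes), and Gpi1 (1.76-fold, adjusted p = 0.0576 over all genes). The median log2 difference of the list was 0.11 (camera adjusted p = 0.167). RNA levels do not measure glycolysis itself, and the test of single genes recovered 12% of simulated 2-fold changes. The list test had more power. In simulated counts for this comparison, camera at the preset correlation called a list of 25 genes raised 1.5-fold (adjusted p = 4.77e-07). It called 0 of 20 unchanged lists, but the simulated genes varied independently of one another. A rise of that size over the whole glycolysis list was not seen. Smaller or partial rises and glycolysis itself stay open, so these counts do not speak against the title. No gene passed over all genes among 20 hypoxia targets (camera adjusted p = 0.683), 20 genes of the tricarboxylic acid cycle (0.455), 24 of the respiratory chain (0.683) or 33 of ribosomal proteins (0.683).

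Of 20 stem cell and hair follicle genes 3 rose in CD34-positive cells, the sort marker gene Cd34, the semaphorin receptor gene Nrp1 (8.11-fold, adjusted p = 0.00834) and Twist1 (7.07-fold, adjusted p = 0.013), and adjusted over the list alone 5 rose and 1 fell. The list tests include Cd34, whose rise reflects the sort. Camera gave this list an adjusted p of 0.0939, of 0.0435 with the animal label as a block, and of 0.753 without the block at an estimated correlation. Its median of -0.06 and its test differ in sign. Of 29 keratinocyte differentiation genes the desmocollin gene Dsc2 rose 3.98-fold (adjusted p = 0.0131), and 8 rose adjusted over the list alone, among them Lypd3, Sbsn and Sprr1a (camera adjusted p = 3.21e-06, with an estimated correlation adjusted p = 0.519). Of 30 cell cycle genes 23 were higher and 1, Ccnd1, rose adjusted over the list alone (camera adjusted p = 0.0135, with an estimated correlation adjusted p = 0.908), and the camera adjusted p was 0.448 without the CD34-negative a6-high library of KO replicate 2. Camera called neither the 20 basal keratinocyte genes (adjusted p = 0.455) nor the 15 genes of epithelial-mesenchymal transition (0.702).

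Markers of other cell types also differed with CD34. All 11 tested endothelial markers were higher in CD34-positive libraries, 0 passed over all genes and 7 rose adjusted over the list alone (camera adjusted p = 2.5e-07, with an estimated correlation adjusted p = 0.268). Plvap, an endothelial membrane protein gene, averaged 10.8 ± 15.9 against 0.538 ± 0.556 CPM (SD, n = 5), with 39.2 CPM in WT replicate 3. The 15 endothelial markers summed to 20.1 to 91.7 CPM in CD34-positive and 6.5 to 15.3 CPM in CD34-negative a6-high libraries. Of 8 fibroblast markers Postn and Thy1 fell and Pdpn rose (camera adjusted p = 0.399), and of 15 macrophage and dendritic cell markers Cd68 rose 2.20-fold (adjusted p = 0.0254; list adjusted p = 0.879, with a median of -0.61 that differs in sign from the test). Of 22 interferon response genes 19 were lower in CD34-positive libraries and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00531, with an estimated correlation adjusted p = 0.753), but the camera adjusted p was 0.633 without the CD34-negative a6-high library of KO replicate 1. Camera called none of the neutrophil and mast cell (adjusted p = 0.102), melanocyte (0.778), skeletal muscle (0.778), sex-linked (0.778), cytokine (0.0939) and immediate early lists (0.0939). With the animal label as a block it called the last 2 of these (adjusted p = 0.0289 and 0.0435). Without the block each had an adjusted p of 0.781 at an estimated correlation. Of the T and natural killer cell markers 2 and of the erythroid markers 0 reached the level for testing.

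Between CD34-negative a6-high and a6-low cells, Mxd1, which encodes an antagonist of Myc that is expressed in differentiating keratinocytes, was the only gene to pass the edgeR test without a block. It fell in a6-high cells (log2 -1.41 ± 0.15 SE, adjusted p = 0.00798), from 77.1 to 142.8 CPM in the 5 a6-low libraries to 25.2 to 46.0 CPM in the 5 a6-high libraries, while 1621 genes had an unadjusted p under 0.05 and DESeq2 called 243. With the animal label as a block, 60 genes passed in edgeR, 8 higher and 52 lower in a6-high cells. Limma with the label as a random block called 30. All 30 cell cycle genes were higher in a6-high cells with a median log2 difference of 0.73, and 0 passed singly (camera adjusted p = 1.27e-16, with an estimated correlation adjusted p = 0.372). Examples are Mcm6 (1.80-fold, adjusted p = 0.251) and Cdk1 (1.86-fold, adjusted p = 0.297). Of 29 differentiation genes 26 were lower with a median log2 difference of -0.78 (camera adjusted p = 8.39e-08, with an estimated correlation adjusted p = 0.372), and the transcription factor genes Grhl3, Ovol1 and Klf4 fell adjusted over the list alone (adjusted p = 0.189, 0.204 and 0.231 over all genes). Of 20 basal genes, which include the sort marker gene Itga6, 17 were higher (camera adjusted p = 9.63e-05, with an estimated correlation adjusted p = 0.625). Without the a6-low library of KO replicate 1 the camera adjusted p of the differentiation and basal lists was 0.187 and 0.336.

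In the same comparison 14 of 15 macrophage and dendritic cell markers were lower in a6-high libraries, and 8 fell adjusted over the list alone, among them Lyz2 and Fcer1g (camera adjusted p = 6.76e-13, with an estimated correlation adjusted p = 0.11). Markers of neutrophils and mast cells (camera adjusted p = 0.000388, with an estimated correlation adjusted p = 0.11), endothelial cells (0.000169, with an estimated correlation adjusted p = 0.372) and melanocytes (0.0399, with an estimated correlation adjusted p = 0.574) were lower too. The endothelial call was lost without the a6-low library of KO replicate 2 (camera adjusted p = 0.0809) and the melanocyte call without that of KO replicate 1 (0.593).

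The a6 result depended on the 2 a6-low libraries with Itga6 at the a6-high level. Without them, a choice made after their values were seen, 217 genes rose and 125 fell in a6-high cells, 342 in all, Mxd1 among them. Itga6 (log2 2.04 ± 0.32 SE), Itgb4 (2.24 ± 0.25), Itgb1 (2.86 ± 0.31), Col17a1 (3.03 ± 0.42), Lamb3 (3.73 ± 0.48) and Krt5 (1.65 ± 0.38) were among those that rose, and the keratin gene Krt79 (-4.78 ± 1.03) and the lipoxygenase gene Alox12e (-3.98 ± 0.67) fell. These genes were named after their values were seen, and the libraries had been set aside by their level of Itga6, so the 342 calls are not independent evidence of an a6 difference. The count was 50 without the a6-low library of KO replicate 2 alone, 2 without the a6-low library of KO replicate 1, that of WT replicate 1 or the a6-high library of WT replicate 2, and 0 without the 3 libraries that express Y-linked genes.

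The series compared SIRT6 KO and WT cells of each population. In each population Eno1b (ENSMUSG00000059040), a near copy of the enolase gene Eno1, was the only gene to pass the edgeR test. It was higher in libraries labelled KO 19.4-fold in CD34-positive a6-high (log2 4.27 ± 0.29 SE, adjusted p = 2.93e-05), 15.5-fold in CD34-negative a6-high (log2 3.96 ± 0.28, adjusted p = 6.47e-05) and 18.8-fold in CD34-negative a6-low cells (log2 4.23 ± 0.29, adjusted p = 3.43e-05). It averaged 93.5 ± 15 CPM (SD) in the 6 libraries labelled KO and 5.25 ± 1.2 CPM in the 9 WT libraries. Counting can exchange reads between Eno1b and Eno1, so its level is uncertain. Eno1 averaged 1607 ± 259 CPM in libraries labelled KO and 2594 ± 536 CPM in WT libraries (adjusted p = 0.652, 0.498 and 0.865 in the 3 populations). Unadjusted, 1112, 1405 and 687 genes had a p under 0.05, and DESeq2 called 27, 38 and 6. The count of 687 lies below the share of 0.05 of tested genes that chance alone would give. In sums per animal label, 2 against 3, Eno1b was again the only gene to pass (log2 4.17 ± 0.21 SE, adjusted p = 0.00794), with 1656 genes at an unadjusted p under 0.05 and 143 called by DESeq2.

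Of the KO comparisons, that of CD34-positive cells gave 2 genes without WT replicate 1 and that of CD34-negative a6-high cells 2 without KO replicate 1. The sums gave 0 genes without WT replicate 1, 2 or 3, where Eno1b kept a log2 of 4.07 to 4.34, 9 without KO replicate 1 and 10 without KO replicate 2. In CD34-negative a6-low cells Eno1b lost its call when only the compared groups were fitted (log2 4.23 in both fits, adjusted p = 0.0747).

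**Figure D3:**
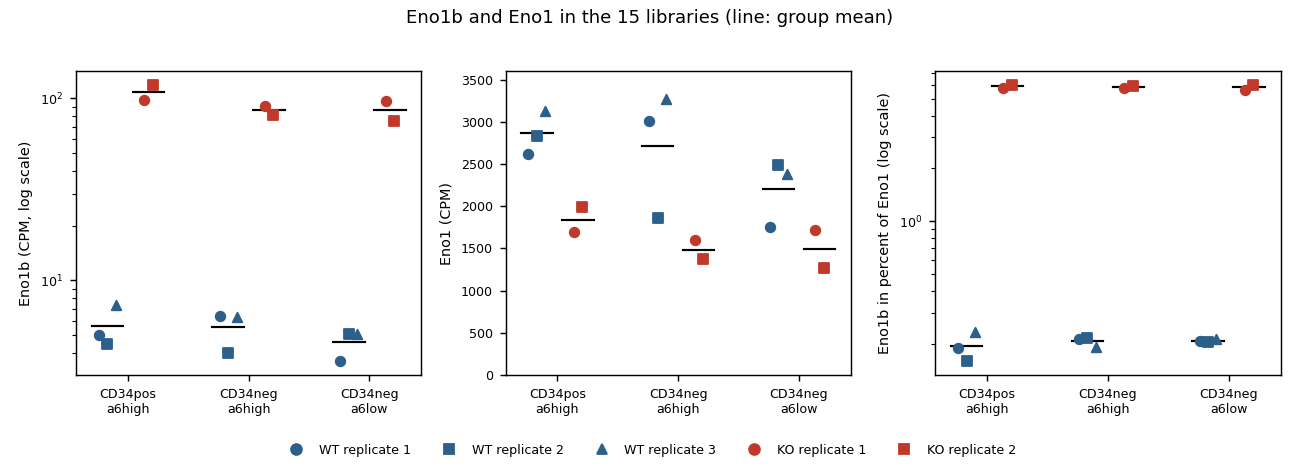
Level of Eno1b (CPM, log axis), level of Eno1 (CPM, linear axis) and Eno1b counts in percent of Eno1 counts (log axis) in the 15 libraries by population, with WT in blue, KO in red, a symbol per replicate number and a black line at the group mean. Eno1b was 5.61% to 5.97% of Eno1 in libraries labelled KO and 0.16% to 0.23% in WT libraries.

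No gene list differed between genotypes with an estimated correlation, and 0 list members passed over all genes. Adjusted over the list alone, 4 macrophage and 2 glutathione genes rose in CD34-positive libraries labelled KO. In CD34-negative a6-high cells 2 macrophage and 2 stem cell genes rose and 1 stem cell gene fell. In a6-low cells 4 melanocyte genes rose. In the sums 1 macrophage, 2 melanocyte, 1 immediate early and 1 stem cell gene rose and 1 stem cell gene fell. Glycolysis genes had median log2 differences, KO minus WT, of -0.09, -0.09 and 0.03 in CD34-positive a6-high, CD34-negative a6-high and CD34-negative a6-low cells (camera adjusted p = 0.571, 0.229 and 0.738), and the last median differs in sign from its test. With the preset correlation, respiratory chain genes were lower in libraries labelled KO in all 3 populations (median log2 -0.38, -0.41 and -0.31, camera adjusted p = 9.3e-05, 1.5e-06 and 0.000136, with an estimated correlation adjusted p = 0.99, 0.677 and 0.626). Ribosomal protein genes were lower as well (median log2 -0.23, -0.23 and -0.23, camera adjusted p = 7.79e-06, 1.3e-05 and 3.31e-06, with an estimated correlation adjusted p = 0.99, 0.677 and 0.491). The respiratory chain call in a6-low cells was lost without KO replicate 2 (camera adjusted p = 0.545), and the ribosomal call in CD34-negative a6-high cells without KO replicate 1 (0.0781).

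Macrophage and dendritic cell markers were higher in libraries labelled KO for 13, 14 and 14 of 15 genes in the 3 populations (camera adjusted p = 8.28e-10, 4.03e-07 and 4.64e-05, with an estimated correlation adjusted p = 0.355, 0.677 and 0.321), at low levels. Libraries labelled KO were also deeper, with means of 23.02 against 16.14 M gene counts, and whether depth affects such low counts was not tested. The lysozyme gene Lyz2 lay at 1.55 and 4.57 CPM in the CD34-positive libraries labelled KO and at 0 in the WT libraries of that population (adjusted p = 0.171), and without the KO replicate 1 library the a6-low list had a camera adjusted p of 0.0897. Interferon response genes were higher in CD34-negative libraries labelled KO for 21 of 22 genes in both populations (camera adjusted p = 1.09e-05 in a6-high and 1.53e-10 in a6-low cells, with an estimated correlation adjusted p = 0.677 and 0.289). Without the KO replicate 1 library of the population the camera adjusted p was 0.675 in a6-high cells, with the direction turned, and 0.0841 in a6-low cells. Melanocyte markers were higher in a6-low libraries labelled KO (camera adjusted p = 1.98e-05, with an estimated correlation adjusted p = 0.289), with 63.1 CPM of Tyrp1 and 52.8 CPM of Dct in KO replicate 1 against at most 1.25 and 2.44 CPM in the other 14 libraries, and without that library the camera adjusted p was 0.266.

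The other lists called between genotypes in single populations with the preset correlation each lost the call with an estimated correlation (adjusted p of 0.289 or more) and without some single library. In CD34-negative a6-high cells, genes of the tricarboxylic acid cycle (camera adjusted p = 0.0223, without KO replicate 1 0.0781) and the cell cycle (0.00794, without KO replicate 2 0.963) were lower in libraries labelled KO, and melanocyte markers were higher (0.0157, without KO replicate 1 0.181). In a6-low cells, cell cycle genes (camera adjusted p = 0.0125, without WT replicate 1 0.9), fibroblast markers (0.0441, without KO replicate 2 0.645), endothelial markers (0.0284, without KO replicate 1 0.5996) and skeletal muscle markers (0.0219, without WT replicate 1 0.276) were lower in libraries labelled KO. Differentiation genes (0.032, without WT replicate 1 0.516) and cytokines (0.000624, without KO replicate 2 0.645) were higher there. In the sums, the calls of the cell cycle, endothelial, interferon, melanocyte and skeletal muscle lists (camera adjusted p = 0.00183, 0.0106, 4.68e-06, 0.00335 and 0.0277, with an estimated correlation adjusted p = 0.745 for each) were each lost without some animal label (0.954, 0.85, 0.971, 0.748 and 0.516). Respiratory chain and ribosomal protein genes were lower in the sums (camera adjusted p = 1.36e-06 for both lists, with an estimated correlation adjusted p = 0.745 and 0.457) and macrophage markers higher in libraries labelled KO (camera adjusted p = 9.13e-12, with an estimated correlation adjusted p = 0.457).

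**Figure D4:**
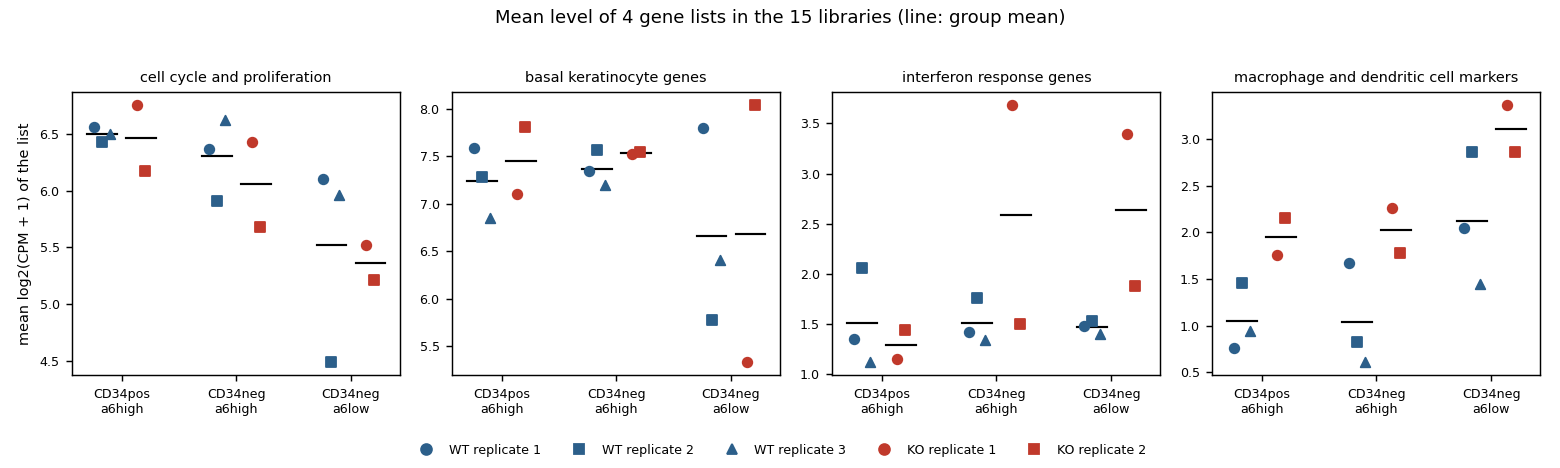
Mean log2(CPM + 1) of the tested members of the cell cycle, basal, interferon and macrophage lists (vertical axis, 1 panel per list) in each of the 15 libraries by population, with WT in blue, KO in red, a symbol per replicate number and a black line at the group mean. The interferon list is highest in the CD34-negative libraries of KO replicate 1.

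Whether the CD34 and a6 differences depended on genotype was tested through interactions. For CD34, edgeR called 0 of 14652 genes, with 159 at an unadjusted p under 0.05, and DESeq2 called 1. For a6, edgeR called 0 genes, with 168 at an unadjusted p under 0.05, and DESeq2 called 0. Both unadjusted counts lie below the share of 0.05 of tested genes that chance alone would give, so they are no sign of interactions. Without a filter on low counts edgeR called 20 and 13. In simulated data with the same groups and no animal effect, 0% of 2-fold and 2% of 4-fold interactions were recovered, so interactions of that size were mostly not detectable.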

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

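The interaction tests were fixed beforehand, and the list tests without single libraries were chosen after the data were seen. With the preset correlation, camera found the CD34 or a6 effect on 5 gene lists to differ between libraries labelled KO and WT libraries, and each call was lost with an estimated correlation.

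The CD34 effect on interferon response genes was lower in libraries labelled KO for 22 of 22 genes (adjusted p = 4.81e-12, with an estimated correlation adjusted p = 0.386), and without the CD34-negative a6-high library of KO replicate 1 the adjusted p was 0.916. The CD34 effect on glutathione and antioxidant genes was higher in libraries labelled KO for 18 of 25 genes (median log2 difference 0.19, adjusted p = 0.00877, with an estimated correlation adjusted p = 0.386), and the adjusted p was 0.242 without the CD34-positive library of WT replicate 2. The CD34 effect on 5 melanocyte markers was lower in libraries labelled KO (adjusted p = 0.00622, with an estimated correlation adjusted p = 0.386), and the adjusted p was 0.38 without the CD34-positive library of WT replicate 1. The CD34 effect on cell cycle genes was higher for 28 of 30 genes (median log2 difference 0.22, adjusted p = 0.0433, with an estimated correlation adjusted p = 0.914), and its direction turned without the CD34-positive library of KO replicate 1 (adjusted p = 0.841) or the CD34-negative a6-high library of KO replicate 2 (0.708). The a6 effect on macrophage and dendritic cell markers was higher in libraries labelled KO for 12 of 15 genes (adjusted p = 0.0113, with an estimated correlation adjusted p = 0.717), and the adjusted p was 0.365 without the a6-low library of KO replicate 2. Fry gave adjusted p = 0.987 for the 4 lists of the CD34 effect and 0.959 for the a6 effect.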

How the results depend on the processing

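Fits without the 2 a6-low libraries, fits without the Y-expressing libraries, limma and list tests in other settings were chosen after the data were seen. Counts of calls moved with most settings, and the cause was not tested. Size factors of DESeq2 in edgeR left every count within 1.5 times and kept all 171 CD34 calls. In the order CD34-positive a6-high, CD34-negative a6-high, CD34-negative a6-low and sums (KO against WT, 1 call each), CD34 (171) and a6 (1), DESeq2 called 27, 38, 6, 143, 853 and 243 genes, and 1 for the CD34 interaction. No filter on low counts gave 195, 256, 156, 6, 1242 and 602, and 20 and 13 for the CD34 and a6 interactions. The stricter filter gave 3 for a6. Fits of the compared groups only gave 2 in CD34-positive and 0 in a6-low cells for KO against WT, 311 for CD34 and 0 for a6, and all 15 libraries in place of sums gave 51. The replicate block gave 2, 2, 2, 0, 793 and 60, and it changed no other count. In list tests, run with it for CD34, a6 and the interactions and not for KO against WT, it ended the a6 melanocyte call (camera adjusted p = 0.0803) and no other, and it added 3 calls each for CD34, a6 and the a6 interaction. Of the 15 libraries 13 correlated best with a library of their own genotype and number, a hint from the data in which the KO replicates mirror each other.

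Leaving out each library gave 1 to 2, 1 to 2 and 1 genes for KO against WT in the 3 populations, 0 to 10 in the sums, 7 to 258 for CD34 and 1 to 50 for a6, and 0 for the interactions. A group left with 1 library was assumed to vary like the others. Without the 2 a6-low libraries at the a6-high level of Itga6 the counts were 370 for CD34 and 342 for a6. Without the Y-expressing libraries they were 4 in CD34-negative a6-high and 6 in a6-low cells for KO against WT, 32 for CD34 and 0 for a6. Limma gave 2, 2 and 3 for KO against WT, 695 for CD34 and 30 for a6. No named gene turned its direction in any setting.

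Of the lists that camera called with all libraries, those whose direction turned without a library had these camera adjusted p, lowest to highest: interferon genes 3.63e-22 to 0.675 (KO, CD34-negative a6-high) and 7.71e-36 to 0.971 (KO, sums), cell cycle genes 4.68e-09 to 0.954 (KO, sums) and 1.21e-05 to 0.841 (CD34 interaction), and, for KO in a6-low cells, differentiation genes 1.64e-11 to 0.516, endothelial markers 0.000115 to 0.5996 and cytokines 8.26e-08 to 0.645. In a6-low cells the cell cycle list turned without the 2 a6-low libraries (0.344) and the cytokine list without the Y-expressing libraries (0.62).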

Other observations

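The tests of a constant or allele-dependent share of Eno1 reads, of sex, of the 2 a6-low libraries and of endothelial cells were chosen after the result was seen, and those of splits, neighbouring genes and library size before.

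Other genes with large differences between genotypes, chosen after their values were seen, did not pass the edgeR test. Rps4l, a copy of the ribosomal protein gene Rps4x, averaged 399 ± 103 CPM (SD) in the 6 libraries labelled KO, with 287 CPM or more in each, and 4.57 ± 4.60 CPM in the 9 WT libraries, with 12.2 CPM or less in each (adjusted p = 0.234, 0.0934 and 0.12 in the 3 populations). Rps4x averaged 532 ± 46.6 and 600 ± 50.5 CPM. Fv1, a retrovirus restriction gene, averaged 4.62 ± 0.70 CPM in libraries labelled KO and 0.985 ± 0.336 CPM in WT libraries (adjusted p = 0.171, 0.356 and 0.865). The predicted gene Gm4735 averaged 45.2 ± 6.87 and 12.7 ± 3.41 CPM (adjusted p = 0.171, 0.356 and 0.0913). Like Eno1b, the genes Rps4l, Fv1 (at least 3.815 against at most 1.331 CPM) and Gm4735 (at least 37.53 against at most 17.95 CPM) were higher in every library labelled KO than in any WT library. Prl2c3, a prolactin family gene, lay at 0.682 CPM or less in libraries labelled KO and averaged 19.2 ± 18.1 CPM in WT libraries, with a range of 0.111 to 47.7 CPM that overlaps that of the libraries labelled KO (adjusted p = 0.206 in the sums). Among the 100 genes of smallest p in the sums, Fv1 (log2 2.20) lay within 10 tested genes of Zfp991 (-2.24), itself within 10 of Zfp990 (5.22), and Prl2c3 (-6.51) within 10 of Prl2c2 (-7.72). Counts of such gene copies are uncertain.

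Eno1b was higher in every library labelled KO than in any WT library. The tables argue against sex, since the lowest level in KO replicate 1, which lacks Y-linked expression, was 12.52 times the highest WT level, and against a share of Eno1 reads that is constant in all mice, since the lowest ratio of Eno1b to Eno1 in libraries labelled KO was 24.1 times the highest WT ratio. Neighbouring genes were not in excess, with 6 neighbouring pairs among the 100 genes of smallest p in the sums against a mean of 6.56 in random sets. Only Eno1b passed in the sums, so nearly all of these 100 genes were not called and the count cannot exclude blocks of background genes. This explanation was narrowed to blocks of genes after that result, and a variant in Eno1 alone is not excluded either. A candidate explanation is a share of Eno1 reads counted for Eno1b that depends on the Eno1 allele of the mouse line: over the libraries labelled KO the log2 ratio of Eno1b to Eno1 had an SD of 0.0361, the lowest of 6564 genes (median 0.372), a test that replaced an undecided earlier one, which set the fall of Eno1 (988 CPM) against the rise of Eno1b (88.2 CPM). An effect of the genotype itself was not tested and stays open.

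The a6-low libraries of WT replicate 1 and KO replicate 2 had Itga6 at the a6-high level. A swap with the a6-high library of the same animal label is argued against by the Itga6 level of these partners, the lower of which was 2.07 times the highest of the other 3 a6-low libraries. The 19 other basal genes lay at their a6-high level too, with median log2 differences of 0.29 in WT replicate 1 and 0.23 in KO replicate 2, against -2.18, -1.9 and -1.01 in the other 3, so these libraries may hold cells of the a6-high kind. The macrophage list, called in the a6 comparison under these same labels and so no independent check of them, had a mean log2(CPM + 1) of 2.05 in WT replicate 1 and 2.86 in KO replicate 2 against 1.67 and 1.78 in the CD34-negative a6-high libraries of the same labels. In the same order, the cell cycle list was lower (6.1 and 5.21 against 6.37 and 5.68) and the differentiation list higher (6.53 and 6.32 against 6.29 and 5.87). The neutrophil and mast cell list was not higher in WT replicate 1 (4.05 against 4.06). Mxd1 was higher in every a6-low library, these included, than in any a6-high library. These calls too rest on the same labels. A wrong label, a swap with a sample outside the series and a difference between tumours were not tested and stay open.

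For the CD34 comparison 1 of the 60 splits of the 10 a6-high libraries within genotypes, the real one, gave as many as 171 calls. The highest other gave 1. These splits ignore the pairs. Among the 16 splits that part every pair the real one again stood alone, and the highest other gave 1. The splits argue against chance, but 16 are too few to exclude it. For the rise of the glutathione genes, endothelial cells are an unlikely source of the summed rise of the 9 genes, 11867 CPM, because the 15 endothelial markers together rose by 27.3 CPM, 0.23% of it; Gsto1 makes up most of that sum (3932 to 11500 CPM), so for genes of low level such as Slc7a11 (9.26 to 78.2 CPM) this source stays open. A difference in library size was not decided by the bound set beforehand, a ratio of at least 1.5 for each of the 9 genes in each pair after thinning to 13.28 M counts. The bound was met by 38 of 45 ratios, 44 were above 1 and the lowest was 0.86 (Cat in WT replicate 2), while mean library sizes differed 1.015-fold (exact permutation test, two-sided, p = 0.929). The CD34-positive library was the larger in 2 of 5 pairs. Though the bound was not met, these values argue against library size as the source of the rise of the 9 genes as a set. A difference between the sorted tumour cells stays open as a hypothesis, as do other cell types beyond the marker lists.

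For the a6 comparison chance cannot be excluded, since 4 of 60 splits gave at least the 1 call of the real split and the highest other gave 2. Among the 16 splits that part libraries of the same label, only the real one gave 1 call and the highest other gave 0. These libraries were not taken as pairs, and 16 splits are too few to exclude chance.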
